A study of Homo sapiens with 6 samples.

How the data were processed

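Total RNA of PLC/PRF/5 cells was extracted with Trizol and made into libraries with the Illumina TruSeq RNA kit, per the labels' protocols. HISAT2 and the genome build GRCh38 are named in the submitters' processing notes. The aligner version, the counting program, the annotation release, the strand setting and any filter are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. The deposited count table holds raw whole-number counts per Ensembl gene, not normalized, for 60623 genes, and no row stands for anything but a gene. The deposited FPKM table holds, for the same genes, fragment counts that the authors divided by gene length and library total. For all 24388 genes with a count in all 6 libraries, the ratio of the tables gave the same gene length in all 6 libraries (relative tolerance 1e-06), a whole number within 0.001 bases, so the FPKM values follow from the counts. Each table has 1 column per library. Columns were assigned by the column codes that the sample titles also carry. Gene positions came from GENCODE v29 on GRCh38, in which 58516 of the gene IDs were found; it may not be the annotation the authors used. Gene symbols and types are those of the deposited tables, in which 93 symbols stood on more than 1 row.

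Libraries were grouped by their labels into 3 labelled ZFP64-OE and 3 labelled control, and no library was left out or regrouped. The main test was edgeR 4.0.16 (R 4.3.3), with genes kept by filterByExpr (minimum count 10, minimum total count 15), TMM scaling, robust dispersion estimates and the quasi-likelihood F-test on the group alone, with Benjamini-Hochberg adjustment over the 19173 genes kept and a threshold of 0.05. The biological coefficient of variation was 0.0857, and the median log2 fold change of all tested genes was -0.0166. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values were scaled by the TMM factors, which lay between 0.963 and 1.05. On simulated counts for the 19173 genes of this comparison, with 100 genes changed 1.5-fold and 100 changed 2-fold, edgeR recovered 76% and 90% of them with 10 false calls. DESeq2 recovered 74% and 87% with 7 false calls, limma-voom 74% and 89% with 7, the fit with a replicate block 79% and 90% with 16, and limma on log2 FPKM 47% and 78% with 5. The changed genes were drawn above a minimum mean CPM, so recovery of genes near the floor was not measured. Counts were simulated independently for each gene, so spread that genes of a library share was left out.

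Replicates of a group differed by more than sampling noise, with a chi-square statistic per gene of at least 10.2 for every pair within a group, so no library was treated as a copy of another. The first principal component of log2 CPM (prior count 2) held 39.4% of the variance and separated the groups; the second held 23.8% and set replicate 1 labelled control apart from the others. No batch is given in the labels.

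The lists of genes were fixed before the data were examined, as were the tests and the rule for the genes named. They are 22 lists of biology (macrophage-directed cytokines, CXC chemokines and NF-kB targets, the protein kinase C family, immune checkpoint ligands, MHC class I presentation, the interferon response, hepatocyte function, fetal liver and progenitor markers, cell cycle, p53 targets, epithelial-mesenchymal transition, Notch, Wnt targets, the unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis and oxidation, TGF-beta and SMAD targets, immediate early genes, MLL complex and HOX genes, heat shock, NRF2 targets), 3 of RNA quality (mitochondrially encoded mRNAs, ribosomal proteins, histones) and 5 of other cell types (macrophages, lymphocytes, fibroblasts, endothelial cells, packaging line cells). The first 25 were tested with camera (limma 3.58.1, on voom values) at a preset correlation of 0.01 between genes, with adjustment over the 25 lists. Camera called 10 lists, 2 higher and 8 lower. With a correlation estimated for each list it called 0, with 1 list, the NRF2 targets, at an unadjusted p under 0.05. Fry, tested for whether a list's genes move one way on balance, called 4, and fry means this test unless its mixed test is named. The mixed test, which counts changes in both directions, also passed lists that camera did not call, such as hepatocyte function (adjusted p = 2.59e-05). It did not pass the ribosomal and mitochondrial lists (adjusted p = 0.0682 and 0.0615). Marker sums of other cell types were compared by exact permutation.

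Genes named are ZFP64, CSF1 and PRKCA; the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and fully separated groups; up to 3 members of each biology list with the smallest p past the threshold; and the 2 most abundant members of each quality and other-cell list. Others were chosen after their values were seen: SERPINA1, APOB, FGB, APOA1, GPC3, LGR5, CXCL2, CXCL5, CXCL8, SPP1, GDF15, TGFB3, GCLM, AKR1C2, AKR1C3, CD274, SLC2A1, SLC2A14, LDHA, DGAT2, KMT2A, the genes of families and of chromosome 4 in the closing section, IGFBP3 and GJA1.

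Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no count filter and a strict filter (at least 50 counts in at least 3 libraries), the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5 and on log2(FPKM + 1) without that filter, each library left out in turn, an estimated correlation and fry for the lists, and, chosen after seeing the data, mitochondrial genes left out of the library sizes. Also chosen after seeing the data were one-sided Fisher tests of the genes called per chromosome and per family of symbols, each in both directions with Benjamini-Hochberg adjustment.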

Results

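RNA was sequenced from PLC/PRF/5, an established human hepatocellular carcinoma cell line, after delivery of a lentiviral vector. Of the 6 libraries, 3 were labelled as carrying a vector that overexpresses ZFP64, a zinc finger transcription factor, and 3 as carrying a control vector. The libraries labelled ZFP64-OE held 38325711, 39739674 and 35109227 counts and the libraries labelled control 26468949, 37466920 and 31455930, for replicates 1, 2 and 3. Between 29075 and 31618 genes had a count in a library. The series title names PKCα, ZFP64 and CSF1 together with macrophage polarization and the response to anti-PD1, and the comparison asks which transcripts differ when ZFP64 is raised in tumour cells. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

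The targeted gene went against the labels. ZFP64 (ENSG00000020256, chromosome 20, 52051663 to 52204308 on the minus strand of GRCh38) was 4.31-fold lower in the libraries labelled ZFP64-OE. Its counts were 1314, 1385 and 1112 in the libraries labelled ZFP64-OE and 3620, 6157 and 4552 in the libraries labelled control. These are 34.1 ± 2.24 against 147 ± 11.8 CPM (counts per 1e6 library counts, scaled by TMM factors; SD, n = 3 each), a log2 fold change of -2.11 with a standard error of 0.0867 and an adjusted p of 2.31e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 3 libraries labelled ZFP64-OE lay below all 3 labelled control. The groups are given here as labelled, and every direction below is that of the libraries labelled ZFP64-OE relative to those labelled control, whatever their true identity.

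CSF1, the growth factor that recruits and maintains macrophages, was 6.14-fold lower in the libraries labelled ZFP64-OE. Its level was 14 ± 0.548 CPM in them and 86.0 ± 4.26 CPM in the libraries labelled control (SD, n = 3 each). The log2 fold change was -2.62 (standard error 0.0824, edgeR adjusted p = 4.09e-14, the smallest of the 19173 genes tested), again with no overlap between the groups. CSF1 (ENSG00000184371) lies on chromosome 1 from 109910242 to 109930992. PRKCA, which encodes PKCα (ENSG00000154229, chromosome 17, 66302636 to 66810743), was measured at 224 ± 19.9 CPM in the libraries labelled ZFP64-OE and 216 ± 13.9 CPM in those labelled control. Its log2 fold change of 0.05 with a standard error of 0.0901 did not pass the test (edgeR adjusted p = 0.818).

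**Figure D1:**
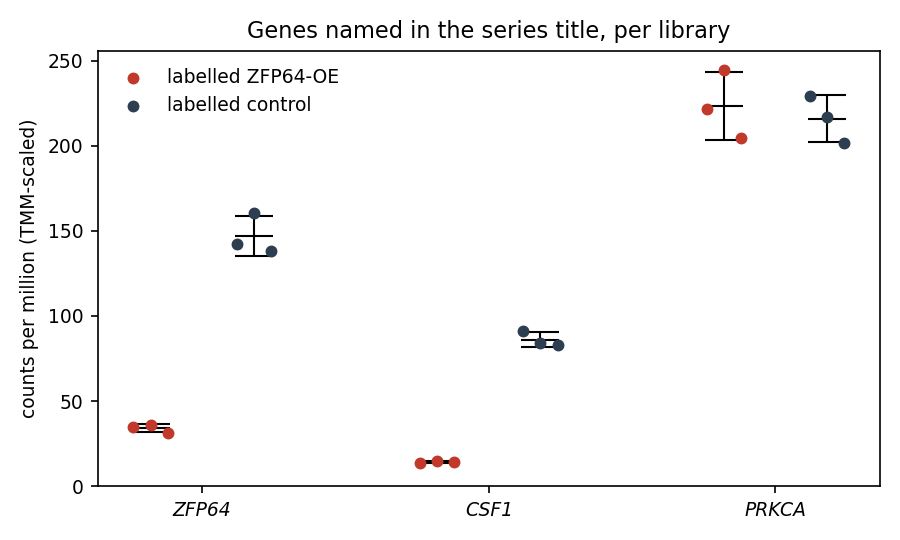
CPM (vertical axis, scaled by TMM factors) of ZFP64, CSF1 and PRKCA in each library (points), with the mean and SD of each group of 3 (bars). The libraries labelled ZFP64-OE lay below those labelled control for ZFP64 and CSF1, and the groups overlapped for PRKCA.

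Genes lower in the libraries labelled ZFP64-OE outnumbered those higher. Of 19173 genes tested, 1114 passed an adjusted p of 0.05 with edgeR, 342 higher and 772 lower, and among the 286 that also differed at least 2-fold, 41 were higher and 245 lower. DESeq2 called 455 higher and 599 lower, a less uneven split of 56.8% lower against 69.3%. With RLE scaling, edgeR called 380 higher and 696 lower, 64.7% lower. The groups were fully separated for 4207 genes, 21.9% of those tested, where 10% is the average over all splits of the libraries. Genes can share spread between libraries, so a share over 10% does not by itself show a group effect. Of the 1114 called, 1095 were separated, which adds no support, since a call with 3 against 3 nearly requires separation. The number of calls depended on single libraries. It was 673 without replicate 1 labelled ZFP64-OE, 735 without replicate 2 labelled ZFP64-OE and 587 without replicate 2 labelled control. The number higher was 524 without replicate 3 labelled ZFP64-OE and 585 without replicate 1 labelled control. Of the 587 genes, 568 were among the 1114.

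**Figure D2:**
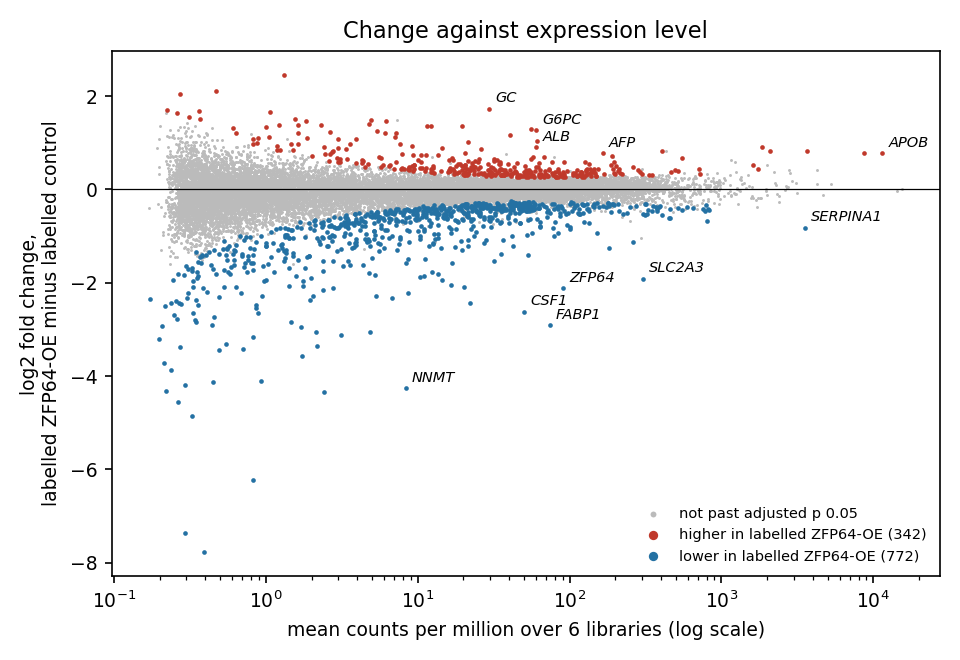
Log2 fold change of the libraries labelled ZFP64-OE over those labelled control (vertical axis) against mean CPM over the 6 libraries (horizontal axis, log scale), 1 point per tested gene. Genes past an adjusted p of 0.05 are red where higher (342) and blue where lower (772), and most of the large differences were falls.

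The largest fall among protein-coding genes past the threshold with a mean of at least 5 CPM and fully separated groups was that of NNMT. It encodes nicotinamide N-methyltransferase, a cytosolic enzyme that consumes methyl groups. NNMT (chromosome 11, 114257787 to 114313285) was at 0.830 ± 0.202 CPM in the libraries labelled ZFP64-OE and 15.8 ± 2.35 CPM in those labelled control, 19.1-fold lower (edgeR adjusted p = 2.31e-12). It was followed by FABP1, the liver fatty acid binding protein, at 17.4 ± 4.81 against 131 ± 30.9 CPM (log2 fold change -2.92, adjusted p = 0.0058), then by CSF1 and by the apolipoprotein gene APOA4 (-2.44, adjusted p = 2.57e-09). P3H3, a collagen prolyl hydroxylase (-2.33), ANXA3, an annexin (-2.28), and SLC1A6, a glutamate transporter (-2.22), came next, and ZFP64 itself was the eighth.

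Rises were ranked among protein-coding genes past the threshold with a mean of at least 5 CPM and fully separated groups. The largest was that of GC, which encodes the vitamin D binding protein of plasma (chromosome 4, 71741693 to 71804041). GC was at 45.4 ± 3.51 CPM in the libraries labelled ZFP64-OE and 13.8 ± 1.74 CPM in those labelled control, a log2 fold change of 1.73 (edgeR adjusted p = 3.04e-10). The next largest were CPLX2 (1.48), a regulator of vesicle fusion, the alcohol dehydrogenase ADH1C (1.36), the mucin MUC3A (1.35), HAL (1.29), which starts histidine breakdown, G6PC (1.27), the catalytic subunit of glucose-6-phosphatase, the ephrin receptor EPHA7 (1.25) and the cation transporter SLC22A3 (1.21). Reads of MUC3A can be shared with neighbouring mucin copies, so its value is uncertain.

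Hepatocyte genes moved in both directions. Of 49 measured members of the list, 8 rose, 8 fell and 33 did not pass (9 and 10 adjusted over the list alone). The risers included ALB, the main plasma protein, at 78.9 ± 7.71 CPM in the libraries labelled ZFP64-OE against 42.0 ± 4.48 CPM (log2 fold change 0.91), the fibrinogen chain FGB at 524 ± 16.6 against 295 ± 19 CPM (0.83) and G6PC. The fallers included APOA4, APOA1 (-0.59) and SERPINA1, the plasma protease inhibitor, at 2576 ± 246 against 4544 ± 765 CPM (-0.82). APOB, the structural protein of very low density lipoprotein and the most abundant of these transcripts, was at 14500 ± 2820 against 8455 ± 2040 CPM (0.78, edgeR adjusted p = 0.00989). The list as a whole passed no test of a shift in 1 direction (camera adjusted p = 0.788), and its median (0.01) and mean (-0.07) differed in sign. It passed fry's mixed test, which counts changes in both directions (adjusted p = 2.59e-05). The APOB call was lost without replicate 2 labelled control (adjusted p = 0.0701), which also left 5 risers on the list.

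Markers of fetal liver and of progenitor cells held more falls than rises. Of 19 measured members, 3 rose, 7 fell and 9 did not pass (5 and 9 adjusted over the list alone; camera adjusted p = 0.0652). SOX9, a transcription factor of biliary and progenitor cells, was at 17 ± 0.249 CPM in the libraries labelled ZFP64-OE and 37.5 ± 1.97 CPM in those labelled control (log2 fold change -1.15, edgeR adjusted p = 9.08e-09). The biliary keratin KRT19 fell by 3.36 on the log2 scale (adjusted p = 1.23e-08), from 3.99 ± 0.471 to 0.388 ± 0.149 CPM. AFP, the fetal counterpart of albumin, was higher, at 209 ± 13.8 against 122 ± 9 CPM (0.77, adjusted p = 5.16e-06). The other risers were LGR5, whose call was lost without 3 of the libraries (highest adjusted p = 0.206), and GPC3, whose call (adjusted p = 0.0354) was lost without 4 (highest 0.204). Only 1 riser was left without replicate 1 labelled ZFP64-OE, replicate 2 labelled control or replicate 3 labelled control, and 2 without replicate 2 labelled ZFP64-OE. Camera called the list lower without replicate 1 or 2 labelled ZFP64-OE (adjusted p = 0.00204 and 0.00328) or replicate 2 or 3 labelled control (adjusted p = 0.0107 and 0.0126).

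Among cytokines and growth factors that act on macrophages, CSF1 stood out by size. Of 17 measured members, 3 rose, 3 fell and 11 did not pass (3 and 5 adjusted over the list alone). LIF fell by 2.12 on the log2 scale (1.04 ± 0.128 CPM in the libraries labelled ZFP64-OE against 4.50 ± 0.991 CPM) and IL18 by 0.56 (edgeR adjusted p = 5.56e-07 and 0.000638). The 3 risers were SPP1, which encodes osteopontin (1.20, adjusted p = 0.00209, at 2.27 ± 0.37 CPM), GDF15 (0.38, adjusted p = 0.0249) and TGFB3, whose call was lost without 5 of the libraries (highest adjusted p = 0.25). The list did not pass camera (adjusted p = 0.134). The only riser left without replicate 2 labelled ZFP64-OE was SPP1, with GDF15 then at an adjusted p of 0.122; the GDF15 call was also lost without replicate 3 labelled control.

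Neutrophil-attracting chemokines made up most of the falls on the list of CXC chemokines and NF-kB targets. Of 24 measured members, 2 rose, 5 fell and 17 did not pass (6 and 7 adjusted over the list alone; camera adjusted p = 0.833). CXCL1, CXCL2, CXCL5 and CXCL6 were among the 5 that fell, with log2 fold changes between -0.42 for CXCL5 and -1.03 for CXCL6 (edgeR adjusted p = 0.0175 and 4.16e-05). CXCL1 was at 96.4 ± 8.54 CPM in the libraries labelled ZFP64-OE and 139 ± 14.6 CPM in those labelled control. ICAM1, an adhesion molecule, was higher (0.43, adjusted p = 0.0052). Neither riser was called without replicate 2 labelled ZFP64-OE, which left 4 calls on the list, and 1 riser was left without replicate 2 labelled control. The ICAM1 call was lost without replicate 2 labelled ZFP64-OE (adjusted p = 0.0638) and that of CXCL5 without that library, replicate 1 labelled control or replicate 3 labelled control (highest adjusted p = 0.0979). CXCL8 did not pass, with a log2 fold change of -0.28 (adjusted p = 0.0984); it passed without replicate 3 labelled ZFP64-OE (adjusted p = 0.0226) or replicate 1 labelled control (adjusted p = 0.0476).

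Of 16 measured ligands of immune checkpoints, 6 fell and 10 did not pass in the libraries labelled ZFP64-OE (1 higher and 8 lower adjusted over the list alone). CEACAM1, a ligand of TIM-3, fell by 0.85 on the log2 scale, NT5E, the ectoenzyme CD73 that makes adenosine, by 0.63, and FGL1, a ligand of LAG-3, by 0.53 (edgeR adjusted p = 1.83e-05, 6.73e-05 and 0.00291). The list was called lower by camera (median log2 fold change -0.34, adjusted p = 0.00135), and the call was lost with an adjusted p = 0.503 with an estimated correlation. CD274, which encodes PD-L1, the ligand of PD1, was at 1.29 ± 0.255 CPM in the libraries labelled ZFP64-OE and 1.61 ± 0.241 CPM in those labelled control, and did not pass (log2 fold change -0.32 with a standard error of 0.225, adjusted p = 0.479).

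The interferon response list was called lower by camera (30 measured, median log2 fold change -0.08, adjusted p = 0.0117), with an adjusted p = 0.503 with an estimated correlation. On it 5 members fell and 25 did not pass (6 lower adjusted over the list alone), among them CMPK2, a mitochondrial nucleotide kinase induced by interferon, which was 11.8-fold lower, at 0.268 ± 0.0141 CPM in the libraries labelled ZFP64-OE against 3.20 ± 0.452 CPM. IFI6 fell by 0.89 and BST2, an antiviral tether, by 0.50 on the log2 scale (edgeR adjusted p = 0.000141 and 0.00106). The list's camera call was also lost without replicate 3 labelled ZFP64-OE (adjusted p = 0.0741). Of 20 genes of MHC class I presentation, 1 passed, the proteasome activator PSME1 (-0.33, adjusted p = 0.0247, lost without 4 of the libraries, with a highest adjusted p of 0.145), while 1 higher and 1 lower passed adjusted over the list alone (camera adjusted p = 0.833). Without replicate 1 or 2 labelled control the 1 call was a rise, and without replicate 3 labelled ZFP64-OE 2 fell.

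On the list of hypoxia and glycolysis, of 35 measured members 10 fell in the libraries labelled ZFP64-OE and 25 did not pass (11 lower adjusted over the list alone), and 34 had a log2 fold change below 0. SLC2A3, the glucose transporter GLUT3, was at 128 ± 14.6 CPM in the libraries labelled ZFP64-OE and 482 ± 70.6 CPM in those labelled control (-1.91, edgeR adjusted p = 6.45e-10); reads can be shared with its near-identical copy SLC2A14, which was also lower (-2.29). EGLN3, an oxygen-sensing prolyl hydroxylase (-3.06), and the carbonic anhydrase CA12 (-2.15) fell as well (adjusted p = 4.4e-08 and 6.89e-05). SLC2A1 and LDHA, abundant glycolytic genes, did not pass (-0.22 and -0.15, adjusted p = 0.301 and 0.506). The list was called lower by camera (median -0.19, adjusted p = 9.72e-11), but the call was lost with an estimated correlation (adjusted p = 0.524) and by fry (0.132). The number of fallers was 5 without replicate 1 labelled ZFP64-OE, and SLC2A1 passed without replicate 3 labelled control (adjusted p = 0.0291).

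The lists of epithelial-mesenchymal transition and of TGF-beta targets held falls and no rises among the calls, and their list calls depended on the test and on single libraries. The first holds epithelial as well as mesenchymal genes, so its call says nothing on the direction of a transition. Of 23 measured genes of epithelial-mesenchymal transition, 7 fell and 16 did not pass (8 lower adjusted over the list alone), including the lysyl oxidase family member LOXL2 and the calcium-binding protein S100A4, which fell by 1.12 and 1.11 on the log2 scale, and the low-level matrix metalloproteinase MMP7 (0.116 ± 0.0392 against 0.793 ± 0.109 CPM). Camera called the list lower (median -0.15, adjusted p = 0.00328), with an adjusted p = 0.503 with an estimated correlation, of 0.0769 without replicate 3 labelled ZFP64-OE and of 0.116 without replicate 1 labelled control. TGF-beta and SMAD targets were also called lower (20 measured, median -0.15, adjusted p = 0.0355), with an adjusted p = 0.58 with an estimated correlation. On this list 5 fell and 15 did not pass (8 lower adjusted over the list alone), SMAD6, an inhibitor of BMP signalling, by 0.46 on the log2 scale (edgeR adjusted p = 0.000373) and the latent TGF-beta binding proteins LTBP1 and LTBP3 by 0.46 and 0.33. The 5 TGF-beta calls came down to 1 without replicate 1 or replicate 2 labelled control, to 2 without replicate 1 labelled ZFP64-OE and to 3 without either of the other libraries labelled ZFP64-OE. The camera call was lost without replicate 3 labelled ZFP64-OE (adjusted p = 0.172) or replicate 1 labelled control (0.228), the LTBP1 call without 3 of the libraries (highest adjusted p = 0.0918) and the LTBP3 call without 4 (highest 0.141).

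Most calls on the Wnt and Notch lists were falls. Of 18 measured Wnt targets, 1 rose, 4 fell and 13 did not pass (1 and 5 adjusted over the list alone; median -0.15, camera adjusted p = 0.0424, and adjusted p = 0.503 with an estimated correlation). The Wnt inhibitor APCDD1 fell by 1.52 and the transcription factor TBX3 by 0.57 on the log2 scale (edgeR adjusted p = 2.09e-05 and 0.000114), and WIF1, another Wnt inhibitor, was near the floor at 0.0278 ± 0.0283 CPM in the libraries labelled ZFP64-OE and 0.555 ± 0.125 CPM in those labelled control. LGR5 was the riser, and its call was lost without replicate 1 labelled ZFP64-OE (adjusted p = 0.0972), replicate 2 labelled control (0.206) or replicate 3 labelled control (0.054). The 5 calls on the list were 3 without replicate 1 labelled ZFP64-OE. The Wnt list's call was lost without replicate 3 labelled ZFP64-OE (adjusted p = 0.0976) or replicate 1 labelled control (0.172). Of 21 measured Notch genes, 3 fell and 18 did not pass (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.101, and 0.0269 without replicate 3 labelled control). DTX4, HEY1 and HES7 fell by 0.53, 0.85 and 1.34 on the log2 scale. The 3 Notch calls came down to 1 without replicate 1 or 2 labelled ZFP64-OE or replicate 2 or 3 labelled control. The call of HES7 (edgeR adjusted p = 0.0495) was lost without any 1 of the 6 libraries (highest adjusted p = 0.3) and that of HEY1 without 5 of them (highest 0.0745).

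The NRF2 list, genes that answer oxidative stress, was the biology list called higher. Of 24 measured members, 12 rose and 12 did not pass (13 higher adjusted over the list alone). OSGIN1, an oxidative stress response gene, rose by 0.62 on the log2 scale, HMOX1, haem oxygenase 1, by 0.51 (236 ± 16.8 CPM in the libraries labelled ZFP64-OE against 166 ± 14.7 CPM) and GCLM, a subunit of the enzyme that limits glutathione synthesis, by 0.48 (edgeR adjusted p = 5.82e-05, 0.00116 and 0.0025). AKR1C1 rose by 0.59 (adjusted p = 6.48e-05), with AKR1C2 and AKR1C3 also among the 12, but these paralogs are nearly identical and their reads cannot be told apart with certainty. The AKR1C2 call (adjusted p = 0.0447) was lost without any 1 of the 6 libraries (highest adjusted p = 0.14) and the AKR1C3 call (0.0417) without 5 of them (highest 0.158). The list was called higher by camera (median 0.24, adjusted p = 6.04e-09), with an adjusted p = 0.503 with an estimated correlation. The number of risers was 5 without replicate 2 labelled control and 7 without replicate 2 labelled ZFP64-OE, while the camera call held without each library in turn (highest adjusted p = 1.62e-06).

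Genes of lipid metabolism fell in part. Of 29 measured genes of fatty acid synthesis and oxidation, 4 fell and 25 did not pass (4 lower adjusted over the list alone; camera adjusted p = 0.745). Among them were FABP1, DGAT2 (lost without 4 of the libraries, with a highest adjusted p of 0.132) and FADS2 (-0.45, edgeR adjusted p = 0.0145, lost without replicate 1 labelled ZFP64-OE or replicate 2 labelled control, with a highest adjusted p of 0.088). The calls came down to 2 without replicate 1 labelled ZFP64-OE or replicate 2 labelled control. Of 24 cholesterol synthesis genes, 2 fell and 22 did not pass (3 lower adjusted over the list alone), TM7SF2 by 0.42 and HSD17B7 by 0.30 on the log2 scale (adjusted p = 0.0144 and 0.0288). Without replicate 2 labelled control both calls were lost (adjusted p = 0.108 and 0.17), as they were without replicate 1 labelled ZFP64-OE, and that of HSD17B7 was lost without 5 of the libraries. Camera called the cholesterol list lower (median -0.13, adjusted p = 0.0117), with an adjusted p = 0.663 with an estimated correlation and of 0.0769, 0.0906 and 0.0717 without replicate 3 labelled ZFP64-OE, replicate 1 labelled control and replicate 2 labelled control.

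Cell cycle genes showed 1 call, the thymidylate synthase gene TYMS, which fell by 0.33 on the log2 scale (edgeR adjusted p = 0.0163, lost without replicate 2 labelled ZFP64-OE or replicate 1 labelled control, with a highest adjusted p of 0.122), while the other 45 of 46 measured did not pass and 1 was lower adjusted over the list alone (camera adjusted p = 0.825). Without replicate 1 labelled control 2 cell cycle genes were called, both higher. Of 21 p53 targets, MDM2 rose by 0.41 and PMAIP1 fell by 0.49 on the log2 scale (adjusted p = 0.00467 and 0.00528), with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.686). The risers were 2 without replicate 3 labelled ZFP64-OE or replicate 1 labelled control, and the fallers 2 without replicate 3 labelled control. Among 10 measured members of the protein kinase C family, edgeR called 0, limma-voom 0 and DESeq2 0 at the adjusted threshold, 2 were lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone (camera adjusted p = 0.758). Without replicate 3 labelled control, 1 of them was called lower.

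Other stress and developmental lists held between 1 and 4 calls each. Of 30 genes of the unfolded protein response, TRIB3 rose by 0.35 on the log2 scale (edgeR adjusted p = 0.027, lost without 3 of the libraries, with a highest adjusted p of 0.172) and 1 was higher adjusted over the list alone (camera adjusted p = 0.833). Without replicate 3 labelled ZFP64-OE 2 of them also fell, and without replicate 2 labelled control 2 rose. Of 31 immediate early genes, 2 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.758), with DUSP4, a MAP kinase phosphatase, falling by 0.58 and the nuclear receptor NR4A3 rising by 0.49 (adjusted p = 4.3e-05 and 0.0104; for NR4A3 0.0866 without replicate 2 labelled control). Only 1 rose and 1 fell without replicate 1 or 2 labelled ZFP64-OE or replicate 3 labelled control. Of 17 heat shock genes, the collagen chaperone SERPINH1 fell by 0.51 and the mitochondrial chaperonin HSPE1 by 0.41 (adjusted p = 0.00024 and 0.035; for HSPE1 lost without 4 of the libraries, with a highest adjusted p of 0.157), and 3 were lower adjusted over the list alone (camera adjusted p = 0.745). Without replicate 1 labelled ZFP64-OE or replicate 1 labelled control 1 heat shock gene rose. Of 23 genes of the MLL complex and the HOX clusters, HOXA13 fell by 1.16 (adjusted p = 0.00357), also the 1 call adjusted over the list alone (camera adjusted p = 0.758). KMT2A, which encodes MLL1, did not pass (log2 fold change 0.09, adjusted p = 0.694). The median, mean and test of the MHC class I, unfolded protein response, fatty acid, heat shock, MLL and protein kinase C lists did not share a sign.

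**Figure D3:**
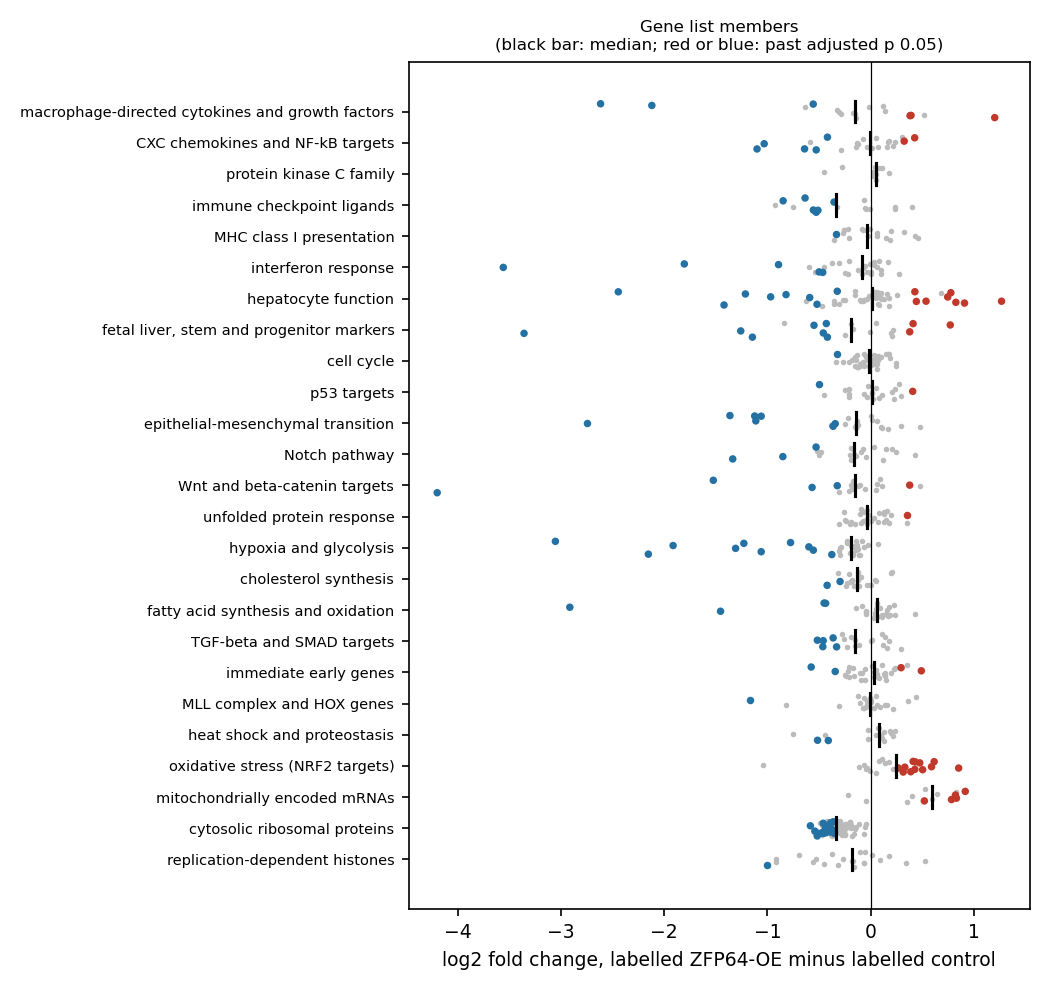
Log2 fold change of the libraries labelled ZFP64-OE over those labelled control (horizontal axis) of each tested member of the 22 biology lists and 3 RNA quality lists (vertical axis). Grey points did not pass an adjusted p of 0.05, red and blue points passed and were higher or lower, and black bars are medians, from -0.34 for immune checkpoint ligands to 0.60 for mitochondrially encoded mRNAs.

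Of the transcript classes used as signs of RNA quality and library make-up, camera called the ribosomal protein and mitochondrial lists and not the histones, and both calls were lost with an estimated correlation and by fry (adjusted p = 0.152 and 0.176). Of 76 measured cytosolic ribosomal protein genes, 19 fell and 57 did not pass (58 lower adjusted over the list alone), all 76 with a log2 fold change below 0 (median -0.33, camera adjusted p = 2.35e-23, and adjusted p = 0.503 with an estimated correlation). The most abundant, RPLP0, was at 2171 ± 256 CPM in the libraries labelled ZFP64-OE and 2633 ± 335 CPM in those labelled control, and neither it nor RPL3 passed (edgeR adjusted p = 0.22 and 0.387). The 19 calls were 1 without replicate 2 labelled control, 2 without replicate 1 or replicate 2 labelled ZFP64-OE and 53 without replicate 3 labelled ZFP64-OE. DESeq2 called 31 ribosomal protein genes lower. Of the 13 mRNAs encoded by mitochondrial DNA, 5 rose and 8 did not pass (11 higher adjusted over the list alone; median 0.60, camera adjusted p = 2.07e-09, and adjusted p = 0.503 with an estimated correlation). MT-CO1 was at 10960 ± 2360 against 6363 ± 1340 CPM (0.78, adjusted p = 0.00786, and 0.0513 without replicate 2 labelled control), and MT-CO2 did not pass (0.41, adjusted p = 0.0988, and 0.025 without replicate 1 labelled control). Mitochondrial genes took 6.22%, 5.05% and 5.21% of counts in the libraries labelled ZFP64-OE and 4.48%, 3.67% and 4.60% in those labelled control. The number of mitochondrial mRNA calls was 3 without replicate 2 or replicate 3 labelled control and 8 without replicate 1 labelled control. Of 22 replication-dependent histone genes 1 fell and 21 did not pass (2 lower adjusted over the list alone; camera adjusted p = 0.121, and 0.0269 without replicate 3 labelled control). The histone call was lost without any library but replicate 3 labelled ZFP64-OE, without which there were 2. The most abundant histone genes, H2AC6 and H4C3, did not pass (adjusted p = 0.761 and 0.109).

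Marker sums of other cell types were compared by exact 2-sided permutation tests, for which 0.1 is the smallest p that 3 against 3 allow. The macrophage and monocyte markers summed to 359 ± 34.8 CPM in the libraries labelled ZFP64-OE and 547 ± 26.1 CPM in those labelled control (exact p = 0.1), and 99.7% of the sum was LYZ, which encodes lysozyme and fell by 0.61 on the log2 scale (edgeR adjusted p = 0.000307). Endothelial markers summed to 5.58 ± 0.974 against 13.9 ± 0.153 CPM (exact p = 0.1), 88.1% of it PECAM1, which fell by 1.49. Fibroblast and stellate cell markers summed to 7.59 ± 0.946 against 10.6 ± 0.807 CPM (exact p = 0.1), with COL3A1 lower (-2.28) and PDGFRB not past the threshold (-0.13, adjusted p = 0.675). Lymphocyte markers were at 0.835 ± 0.108 against 0.853 ± 0.183 CPM (exact p = 0.9), and genes of neural and embryonic kidney cells, from which lentivirus packaging lines derive, at 37.3 ± 0.922 against 37.3 ± 3.16 CPM (exact p = 1). Of 6 tested genes of this last list 1 rose and 1 fell: INA, 49% of the sum, did not pass (0.14, edgeR adjusted p = 0.463), and SALL1 fell by 0.54 on the log2 scale (adjusted p = 0.0205, lost without 3 of the libraries, with a highest adjusted p of 0.0957).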

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

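Apart from the library sizes without mitochondrial genes, chosen after seeing the data, all alternatives were set before the data were examined. ZFP64 and CSF1 were lower past the threshold, and PRKCA was not past it, under all of these alternatives and without each library in turn. RLE, upper-quartile factors, limma-voom and library sizes without mitochondrial genes kept the total counts of genes called, higher, lower and at least 2-fold within 1.5 times. The count of lists called also stayed within it, except that lists were not run with limma-voom. Counts within a list or family moved more, as with 3 mitochondrial mRNAs called by limma-voom against 5 by edgeR. No named gene or list past the threshold was called in the other direction under any setting. DESeq2 shared 892 of its 1054 calls with the 1114 of edgeR. The cause of the differences below was not tested, except where fewer genes or samples were used by construction.

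The numbers of calls changed as follows. DESeq2 gave 190 genes changed at least 2-fold, 156 of them lower. With no count filter 1511 genes were called, 518 higher, and the strict filter, which tests fewer genes, left 150 changed at least 2-fold, 122 lower. On log2(FPKM + 1) 295 genes were called, 78 higher and 217 lower, of which 40 at least 2-fold (6 higher, 34 lower). On log2(FPKM + 0.1) there were 314 (88 higher, 226 lower), of which 105 at least 2-fold (19 and 86), and on log2(FPKM + 1) without the FPKM filter 111 (28 and 83), of which 30 at least 2-fold (4 and 26). With 1 library left out, 587 to 1535 genes were called, 160 to 585 higher and 427 to 1011 lower, and 5 to 13 lists.

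Named genes past the threshold also lost calls. Of 85 measured at the FPKM filter, 42 lost them on log2(FPKM + 1), among those named in the text AKR1C2, AKR1C3, APOA1, APOB, BST2, CXCL1, CXCL2, CXCL5, DGAT2, DTX4, FADS2, FGL1, GDF15, GPC3, HMOX1, HSD17B7, HSPE1, ICAM1, IFI6, IL18, KRT81, LGR5, LOXL2, LTBP1, LTBP3, MDM2, MT-CO1, NR4A3, PMAIP1, PSME1, SALL1, SPP1, TGFB3, TM7SF2 and TRIB3. On log2(FPKM + 0.1) 38 lost them, all among these 42. Without the filter 71 of 100 did, all 42 among them, and also AKR1C1, APCDD1, CA12, CEACAM1, COL18A1, COL3A1, COL4A5, EGLN3, EPHA7, GCLM, HAL, HES7, HEY1, HOXA13, KRT7, KRT80, LIF, LYZ, MMP7, MUC3A, OSGIN1, S100A4, SERPINA1, SLC2A14, TYMS and WIF1. DESeq2 did not call DGAT2, HES7, HEY1, LTBP3, MMP7 or WIF1, RLE did not call HES7, upper-quartile factors HES7, HSPE1 or TGFB3, the strict filter AKR1C3, HSPE1 or TGFB3, limma-voom AKR1C3, and without a count filter HES7 was not called.

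With the replicate number as a block, 2096 genes were called, 749 higher and 1347 lower, including all 1114, and the macrophage cytokine and fetal liver lists passed (adjusted p = 0.0353 and 0.0338). Same-numbered libraries did not deviate together (correlations of 0.0183, 0.0198 and 0.0968 across genes for numbers 1, 2 and 3, none over 0.1), not every library correlated best with its own number, and the numbers were not taken as pairs.

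The list calls changed as follows, in camera adjusted p unless stated. With DESeq2's scaling the Wnt list was at 0.0959, TGF-beta at 0.0891 and histones at 0.0301. With no count filter fetal liver was at 0.00917, and with the strict filter Wnt was at 0.162. On log2(FPKM + 1) interferon was at 0.107, Wnt at 0.0706 and histones at 0.0134; on log2(FPKM + 0.1) these were 0.118, 0.0502 and 0.0133. Without the FPKM filter fetal liver was at 0.0248, Notch at 0.0183 and histones at 0.0288. With an estimated correlation 0 lists passed: checkpoint, interferon, epithelial-mesenchymal, Wnt, NRF2, mitochondrial and ribosomal lists were at 0.503, hypoxia at 0.524, cholesterol at 0.663 and TGF-beta at 0.58. By fry 4 lists passed, macrophage cytokines, Wnt and NRF2 at 0.0205 each and checkpoint ligands at 0.0379. Lists called by camera but not by fry were interferon at a fry adjusted p of 0.0752, epithelial-mesenchymal at 0.126, hypoxia at 0.132, cholesterol at 0.209, TGF-beta at 0.132, mitochondrial at 0.176 and ribosomal at 0.152. With 1 library left out the range was 0.000451 to 0.0741 for interferon, 0.00204 to 0.228 for fetal liver, 0.000157 to 0.116 for epithelial-mesenchymal, 0.0269 to 0.297 for Notch, 0.0107 to 0.172 for Wnt, 0.000758 to 0.0906 for cholesterol, 0.00902 to 0.228 for TGF-beta and 0.0269 to 0.291 for histones. No list test was run with limma-voom as an alternative, since camera already used its values.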

Other observations

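Among what follows, the gene families, the counts per chromosome, the ZFP64 tests and the test of the ribosomal protein list in other splits were chosen only after results were seen.

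Among collagen and keratin genes, more were called lower in the libraries labelled ZFP64-OE than their share of the tested genes gives. Of 19 tested collagen genes 9 fell (one-sided Fisher adjusted p = 5.07e-05 over 169 families in both directions), while COL5A3 rose by 0.74. Among the 9 were COL4A5 (log2 fold change -2.47), the low-level COL3A1 (-2.28, at 0.692 ± 0.0736 against 3.38 ± 0.416 CPM) and COL18A1 (-0.45, at 35.8 ± 3.16 against 49.0 ± 1.4 CPM). COL3A1 is also a marker of fibroblasts and stellate cells, whose marker sum was lower too (7.59 ± 0.946 against 10.6 ± 0.807 CPM), and was the 1 of its 4 tested markers that passed. Of 13 keratin genes 6 fell (adjusted p = 0.0027), including KRT19, KRT81 (-1.21), KRT7 (-1.26) and KRT80 (-0.87). COL4A5, KRT7 and KRT81 had too few counts to be tested with the strict filter. The KRT7 call was lost without replicate 2 labelled control (edgeR adjusted p = 0.101) and the KRT80 call without replicate 1 labelled ZFP64-OE (0.0557). With 1 library left out, 6 to 9 collagens and 5 or 6 keratins fell, and with RLE, upper-quartile factors or DESeq2 6 to 8 collagens and 6 keratins. Families whose calls rested on single libraries were genes whose symbols start with RPS (41 tested, adjusted p = 0.000869, 11 lower, 2 without replicate 1 labelled ZFP64-OE, 1 without replicate 2 of either group and 25 without replicate 3 labelled ZFP64-OE), aldo-keto reductases (0.00672, 4 higher and at most 2 without any 1 library) and semaphorins (0.0487, 5 lower, at most 3 without any 1 library and 2 with RLE, upper-quartile factors or DESeq2).

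IGFBP3 and GJA1, abundant genes outside the lists, fell as well. IGFBP3, which binds insulin-like growth factors, was at 29.2 ± 0.741 CPM in the libraries labelled ZFP64-OE against 77.6 ± 8.1 CPM (-1.41, edgeR adjusted p = 6.45e-10), and GJA1, the gap junction protein connexin 43, at 107 ± 8.35 against 256 ± 26.8 CPM (-1.25, adjusted p = 1.62e-08). Both calls held without each library in turn (highest adjusted p = 2.44e-08 and 9.38e-08).

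ZFP64 was lower in the 3 libraries said to overexpress it. A copy number loss over most of the region within 2 Mb of the gene is argued against by its neighbours. There, 26 other tested genes had a median log2 fold change of -0.0222 (95% bootstrap interval -0.126 to 0.0873). A loss confined to ZFP64 would leave this median unchanged, so the neighbours cannot decide on it. An exchange of the labels between the groups may explain the lower ZFP64. CSF1, also named in the title, was lower with no overlap (-2.617), a value already seen when that test was written. Lower CSF1 cannot tell an exchange from libraries of another experiment in which ZFP64 was lowered. A construct left uncounted while the endogenous transcript fell stays open too. The count table holds 0 entries for a construct, but its rows are Ensembl genes only, so that absence tests nothing. The sources used here do not say whether reads of the construct would be counted on ZFP64. Libraries from another experiment, in which ZFP64 was lowered, were not tested for and stay open as well.

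Of 76 ribosomal protein mRNAs 19 were called lower, and of 13 mitochondrial mRNAs 5 higher, in the libraries labelled ZFP64-OE; both list calls were lost with an estimated correlation (adjusted p = 0.503) and by fry (0.152 and 0.176), and the 19 came down to 2 without replicate 1 or 2 labelled ZFP64-OE and 1 without replicate 2 labelled control, and were 53 without replicate 3 labelled ZFP64-OE. For the ribosomal protein list, bias by transcript length or GC content, each taken alone, is argued against. Genes matched in level and length, or in level and GC content, had medians of 0.00433 and 0.0281 against -0.332 for the list. The match in level was incomplete, with a median of 249 and 272 CPM against 349 CPM for the list. Length and GC content were not matched together. An effect of 1 library alone is argued against by a median of -0.237 at the highest with any 1 left out. Leaving out 1 at a time cannot exclude a pattern carried by 2 libraries. The list's mean log2 CPM, centred on the 6 libraries, was lowest in replicate 1 labelled ZFP64-OE (-0.356) and highest in replicate 2 labelled control (0.307). It was 0.0548 in replicate 3 labelled ZFP64-OE and 0.0707 in replicate 1 labelled control. A spread between libraries that is not tied to the group stays open. Camera called the list in 6 of the 9 other ways to split the libraries, but each of these sets 2 libraries of a group against 1. While 5 of the 6 calls went the way a group effect would, all 6 were lower on the side of replicate 1 labelled ZFP64-OE. The splits therefore cannot tell a group effect from the low level of that library. Setting replicates 1 and 2 labelled ZFP64-OE with replicate 3 labelled control gave a camera adjusted p of 9.28e-31. The labelled split gave 2.35e-23. An effect in which the ZFP64 vector differs from the control vector stays open too, while an effect that both vectors share cannot separate the groups. The mitochondrial list was not tested for these explanations.

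Chromosome 4 held 10.8% of the 342 genes higher in the libraries labelled ZFP64-OE but 3.49% of the genes tested (one-sided Fisher adjusted p = 5.42e-08 over 46 tests), and 8.72% to 11.5% with 1 library left out. It held 37 genes higher and 28 lower, the latter no excess (one-sided Fisher adjusted p = 0.935), and its median log2 fold change was 0.0235. These counts were 20 and 21 without replicate 1 labelled ZFP64-OE and 18 and 17 without replicate 2 labelled control. They were 54 and 38 without replicate 3 labelled ZFP64-OE. Without members of the hepatocyte and fetal liver lists, such as ALB, AFP and FGB, chromosome 4 held 9.97% of the genes higher against 3.47% of those tested (Fisher p = 5.81e-08). GC and ADH1C, liver genes there that also rose, are on neither list, so liver genes on chromosome 4 stay open as an explanation. A segment of changed copy number may still be present, as the highest median of a 10 Mb window was 0.114 but the intervals of 2 windows reached 0.232 and 0.274. Genes on chromosome 4 that together answer a difference between the ZFP64 vector and the control vector stay open as well.

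The 6 libraries can be split into 3 and 3 in 10 ways, too few to judge the counts of calls by. The labelled split gave 1114 genes and the highest other split 0 (edgeR, the only tool run on the splits, with 169 to 3066 genes at an unadjusted p under 0.05 in the others), so that 1 split was as large. For genes changed at least 2-fold these were 286 and 0, again 1 split, and for lists called by camera 10 and 15, with 3 splits as large.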
